A study of Lolium perenne with 10 samples.

How the data were processed

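RNA-seq of leaf tissue from perennial ryegrass (Lolium perenne), a cool-season forage and turf grass, was analysed in 10 libraries that form 5 groups of 2. Per the labels, each library came from 30 seedlings grown at 22 °C by day and 18 °C by night, with 16 h of light at 150 µmol per m2 per s and 65% relative humidity. The groups were untreated control, drought, submergence and a pair of temperature treatments. Drought meant 7 days without water from an age of 7 days. The temperature treatments lasted 12 h and were given to seedlings 14 days old, one group at 4 °C and the other at 42 °C. The duration and depth of submergence and the age of control and submergence seedlings are not given in the sources used here. Comparisons with control may therefore include a difference in age, which was not tested.

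The labels of the temperature groups contradict each other. One pair of libraries has cold in its titles and heat in its treatment field, and the other pair has heat in its titles and cold in its treatment field. Both pairs were kept as groups, called title-cold and title-heat after their titles, and neither was assigned a temperature. The labels' treatment protocol speaks of Arabidopsis and the extraction protocol of bermudagrass, while the organism field gives perennial ryegrass, so protocol details could belong to other experiments. Nothing in the labels says that the replicates of a group were grown as separate cultures beyond their own seedlings, so p-values measure the spread between these libraries, which can in part be technical.

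The authors deposited a table of whole-number read counts for 46394 genes, of which 1 had 0 counts in every library. It is named for perennial ryegrass and, within that, for bermudagrass and cold. Its columns match the sample descriptions of this series, so the counts were taken as perennial ryegrass. Whether they belong to another species or experiment was not tested. RSEM and DESeq 1.10.1 are named per the submitters' processing notes, with no role given. If the deposited counts came from RSEM, they are estimated counts rounded to whole numbers, and reads shared between similar sequences were split between them. The assembly and the aligner are not given in the sources used here. Gene identifiers have the form of assembled sequence clusters, and the files do not pair them with gene names. None of them was found among the 56406 genes of the Kyuss_2.0 reference gene table (0 matches). The 14 gene lists fixed beforehand (heat shock proteins, heat shock factors, cold response, dehydration and abscisic acid response, low oxygen response, photosynthesis, senescence, fructan and starch, oxidative stress, ribosomal proteins, dividing cells, root markers, fungal endophyte and housekeeping genes) therefore had 0 members matched, and their tests are void. Clusters of similar sequence, such as members of a gene family or alleles of this outcrossing species, could not be told from separate genes.

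Total counts per library ran from 10847727 to 12605087. Libraries of one group correlated across genes at r = 0.953 to 0.975 on the log2 scale and differed by more than sampling noise, with a chi-square per degree of freedom of at least 7.71, so each was counted as a replicate. Genes are not independent replicates in such a correlation.

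Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr at its minimum count of 10 and minimum total of 15, which left 27571 genes (59.4%) holding at least 99.24% of the counts of each library. Libraries were scaled with TMM factors, and one quasi-likelihood model with robust dispersions was fitted to all 10 libraries with a coefficient per group. It has 5 residual degrees of freedom. The common dispersion was 0.0899, a biological coefficient of variation of 30%. The 5 contrasts tested were each treatment against control and title-heat against title-cold, and genes with a Benjamini-Hochberg adjusted p below 0.05 were called. Levels are given as CPM, counts scaled to library depth and TMM factor, computed here from the deposited counts, as mean ± SD. The filter of 1 CPM and the levels of genes read only under submergence use depth without the factor.

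A fitted fold change of a gene with 0 counts in one group depends on the prior count. Sizes are therefore given with such genes at a bound, the mean CPM of the other group over the CPM of 3 counts per library. Intervals and floors cover counting error only. By the rule for naming genes, the 2 genes with the largest rise and the 2 with the largest fall over the 4 comparisons with control were named. They had to be called, reach 5 CPM in the higher group and have both libraries of one group above both of the other. Other genes are described in groups defined by their pattern of calls. The groups, the tests of the comparisons, the naming rule and most alternatives were fixed before the data were examined. Some tests of technical explanations were chosen later, as stated with them.

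The 4 comparisons with control share their control libraries. In 20 simulated data sets all 10 libraries, the controls included, were drawn anew with no gene changed. The overlap of independent lists (n1 × n2 / N, per direction) was computed. The procedure was also tested on simulated counts for drought against control. With 200 genes changed, 0% of 2-fold changes (among 23821 genes) and 54% of 4-fold changes (among 23782 genes) were recovered. With 5000 changed, 33.6% of 2-fold changes (among 23635 genes) and 78.3% of 4-fold changes (among 23580 genes) were recovered, and 3.45% of calls fell on unchanged genes at either size. With 200 genes changed 4-fold, 9 calls (7.69%) fell on unchanged genes, a share above the threshold of 0.05. Small changes are therefore often missed with 2 libraries per group.

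The alternatives were DESeq2 1.42.0, limma-voom (limma 3.58.1), RLE and upper-quartile factors, total counts without factors, no filter and a filter of 1 CPM in 4 libraries, only the 2 groups compared, the replicate number as a block, a test against a fold of 1.5, and leaving out each library. Fits without the submergence libraries, and without genes read only or almost only in them (at most 3 counts over the other 8 libraries), were added after seeing the data.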

Results

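Transcript levels were measured by RNA-seq in leaves of perennial ryegrass seedlings under drought, submergence and a pair of temperature treatments, beside untreated controls, with 2 libraries per group. The series asks how the transcriptome of this grass responds to abiotic stress. Total counts were 10847727 and 11265620 in the control libraries, 11319380 and 11398828 under drought, 10900814 and 12605087 under submergence, 10963004 and 11479502 in the title-cold group, and 11425066 and 11008169 in the title-heat group. Title-cold and title-heat name the temperature groups by their titles, and their treatment fields say the reverse, so no temperature is attached to either. Genes are assembled sequence clusters without names, so responses are described by groups of genes.

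In a principal component analysis the first component held 47.5% of the variance, the second 21.7% and the third 11.3%. Drought and title-heat libraries lay together on the first and second components, and they separated on the third, at −102.1 and −106.1 for drought and 103.7 and 114.6 for title-heat. Across genes, libraries of one group correlated at r = 0.953 to 0.975, submergence libraries correlated with the other groups at 0.664 to 0.71, and libraries of the other groups correlated with each other at 0.816 to 0.904. The submergence libraries thus stood farthest from the rest.

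**Figure D1:**
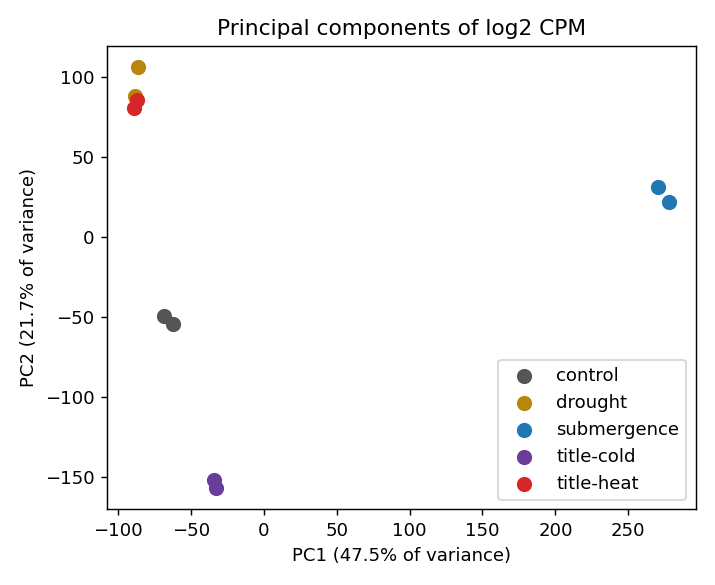
Principal components of the 10 libraries on the log2 CPM scale, one point per library, coloured by group. On the first component (47.5% of the variance) and the second (21.7%) the submergence, title-cold and control pairs stand apart, while drought and title-heat libraries overlap.

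Submerged leaves carried reads from many more genes than any other group. Genes with at least 10 counts numbered 26010.5 ± 61.5 (SD, n = 2) under submergence, against 18426 ± 491 in control, 18720 ± 116 under drought, 20958 ± 629 in title-cold and 17970 ± 322 in title-heat. The difference was much larger than the spread between replicates and was present at equal depth, where submergence had 25453.5 ± 677 and control 18357 ± 393. In all, 3895 genes had at least 10 counts in both submergence libraries and 0 in each of the other 8, and the corresponding numbers were 0 for control, 14 for drought, 5 for title-cold and 13 for title-heat. These submergence-only genes were mostly of low level, with a median of 2.56 CPM and a maximum of 173 CPM by total counts, and held 2.2 ± 0.11% of the counts there. A count of 0 in a library allows up to 3 counts.

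**Figure D2:**
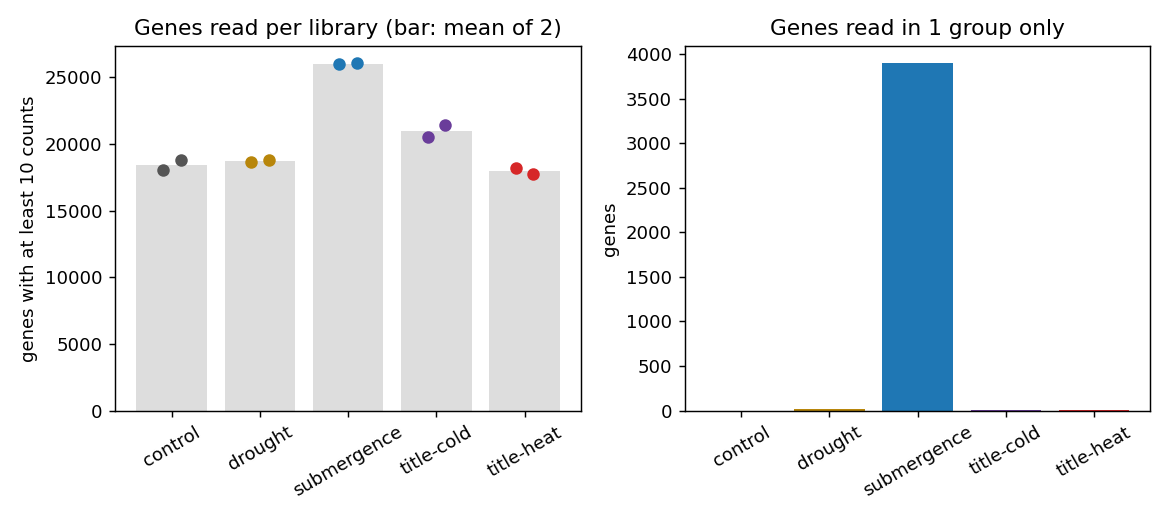
Left, genes with at least 10 counts, with points for libraries and bars for group means, and right, genes with at least 10 counts in both libraries of a group and 0 in the other 8. Submergence has a mean of 26010.5 genes on the left, against 17970 to 20958 in the other groups, and 3895 genes on the right.

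Submergence changed more genes than the other treatments. Of 27571 genes tested against control, 13601 (49.3%) were called by edgeR's quasi-likelihood test, 8885 higher and 4716 lower. With genes at 0 in one group set at their bound, the median change was 2.23 on the log2 scale among the higher genes and −1.75 among the lower, and 7717 higher and 3812 lower genes changed at least 2-fold. Among the higher genes, 4031 had 0 counts in both control libraries. Of the 23921 tested genes outside the submergence-only set, 9951 (41.6%) were called, 5235 higher and 4716 lower. Genes of the set have 0 counts in control by definition and can only be called higher, so this split says nothing further about the balance of the response.

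By fitted log2 fold change, the naming rule took 4 genes, each from submergence against control. For genes at 0 in one group the fitted value depends on the prior count, so their order by true size is not known. The cluster c159807.graph_c0 had 43310 and 44586 counts under submergence and 0 in both controls, a level of 2800 ± 95.7 CPM (SD, n = 2) that was at least 8908-fold higher (adjusted p = 1.02e-05, edgeR). The cluster c123165.graph_c0 reached 961 ± 129 CPM with 0 counts in both controls, at least 3063-fold higher (adjusted p = 1.61e-06, edgeR). At far lower levels both were also called higher than control in title-cold, with 36 and 9 counts for c159807.graph_c0 (adjusted p = 0.0264, edgeR) and 20 and 17 for c123165.graph_c0 (adjusted p = 0.00108, edgeR). In title-heat c123165.graph_c0 was called higher too, with 8 and 6 counts (adjusted p = 0.00408, edgeR). RNA of another organism stays open for genes without reads in control, as described below. Neither of these clusters is therefore known to be a ryegrass gene. Among falling genes, c141899.graph_c0 went from 27.1 ± 6.64 CPM in control to 0 counts in both submergence libraries, at least 141.8-fold lower (adjusted p = 6e-06, edgeR). It also fell to 0 and 1 counts in title-cold (adjusted p = 1.05e-05), while it rose to 58.7 ± 7.9 CPM under drought (adjusted p = 0.0095) and to 121 ± 17 CPM in title-heat (adjusted p = 0.000491). The cluster c82852.graph_c0 went from 105 ± 13 CPM to 0 and 1 counts under submergence, a ratio of 3311 with a counting interval of 593.5 to 130800 (adjusted p = 0.000141, edgeR), and to 4.52 ± 2.21 CPM in title-cold (adjusted p = 0.00201). Its levels of 264 ± 220 CPM under drought (adjusted p = 0.122) and 223 ± 61.5 CPM in title-heat (adjusted p = 0.224) did not pass the test.

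**Figure D3:**
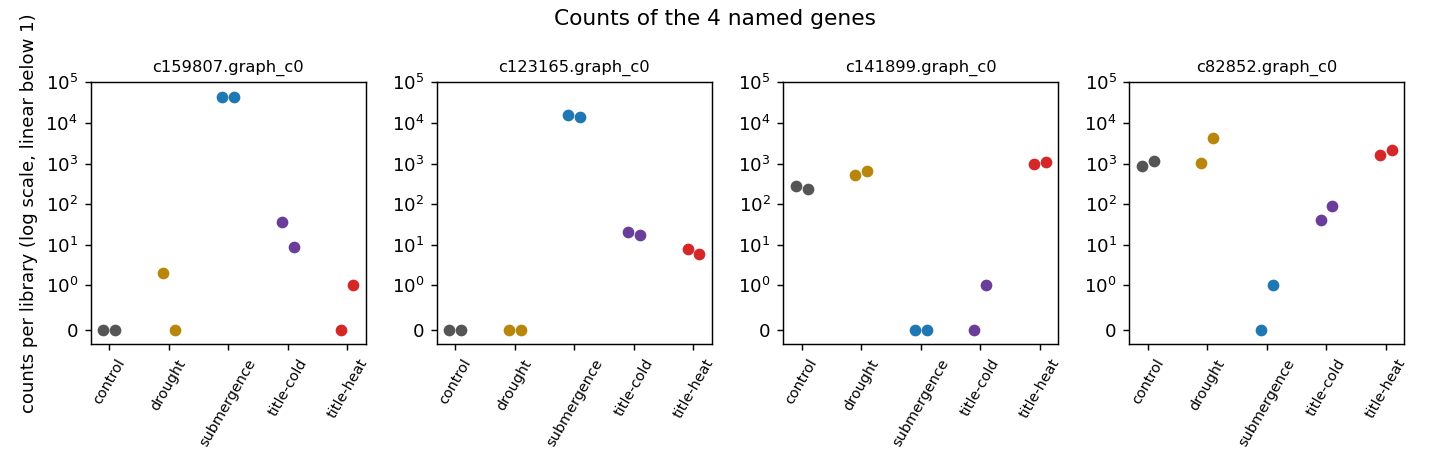
Deposited counts of the 4 named clusters in each library, by group, on a log axis that is linear below 1, with 1 point per library. Under submergence c159807.graph_c0 has 43310 and 44586 counts and c141899.graph_c0 has 0 in both libraries.

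Genes called under submergence numbered 13550 with RLE factors, 13566 with upper-quartile factors and 15610 with total counts, against 13601 with TMM. The balance of higher and lower calls moved with scaling. Calls fell when any library of the comparison was left out, which lowers the power of the test, so this does not single out a library. Without submergence replicate 1 or 2 the count of called genes was 7934 or 8182, and a filter of 1 CPM in 4 libraries, which removes genes read in 1 group alone, gave 8640. It was mainly the higher calls that moved, to 4588 or 4653 without submergence replicate 1 or 2, 5540 or 5649 without control replicate 1 or 2 and 4998 with DESeq2, while the lower calls numbered 3346 to 3750 with a library left out. With total counts in place of TMM factors 81.3% of calls were higher, against 65.3%.

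Drought raised more genes than it lowered. Against control, 7417 genes (26.9%) were called, 4194 higher and 3223 lower, of which 3358 higher and 2256 lower genes changed at least 2-fold. The median change was 1.82 on the log2 scale among the higher genes and −1.31 among the lower. In 207 of the higher genes both control libraries had 0 counts, and in 117 of the lower genes both drought libraries had 0. The excess of higher genes turned with upper-quartile factors, where 44.4% of calls were higher against 56.5%. Without control replicate 1 or 2 the calls numbered 4709 or 4463, and over the 4 libraries left out in turn the higher calls numbered 2579 to 3430 and the lower 1809 to 2465.

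The title-cold group had slightly more falling than rising genes. Against control, 6413 genes (23.3%) were called, 3047 higher and 3366 lower, with 2352 higher and 2448 lower by at least 2-fold. Median changes were 1.54 and −1.41 on the log2 scale. The most-read gene of each library held 8.8 ± 1.1% of the counts against 4.66 ± 0.49% in control, while the 10 most-read genes held 22.5 ± 0.71% and 22.5 ± 2.1% (SD, n = 2). With total counts the share of higher calls was 78.9% in place of 47.5%, so its direction of change on balance depends on scaling. The calls numbered 3727 or 4125 without control replicate 1 or 2 and 4082 without title-cold replicate 2, and over the 4 libraries left out in turn the higher calls numbered 1315 to 1892 and the lower 2315 to 2543.

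The title-heat group differed from control in 5681 genes (20.6%), 3383 higher and 2298 lower. At least 2-fold changes were found in 2661 higher and 1733 lower genes, with median changes of 1.86 and −1.66 on the log2 scale. The share of higher calls, 59.5%, was 49% with upper-quartile factors and 48.3% with total counts. With any library of the comparison left out, fewer genes were called, and the lower calls fell by a larger share than the higher. A group of 1 library has less power, so this does not single out a library.

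Compared directly, the temperature groups differed in more genes from each other than either did from control. Title-heat against title-cold gave 10307 called genes (37.4%), 5392 higher and 4915 lower in title-heat, with 4315 and 4036 of them changed at least 2-fold. Median changes were 1.89 and −1.82 on the log2 scale. The nearly even split was 24.6% higher with total counts against 52.3%. Without title-heat replicate 1 or 2 the calls numbered 6525 or 6719, and over the 4 libraries left out in turn the lower calls numbered 2441 to 3478 and the higher 3980 to 4463.

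**Figure D4:**
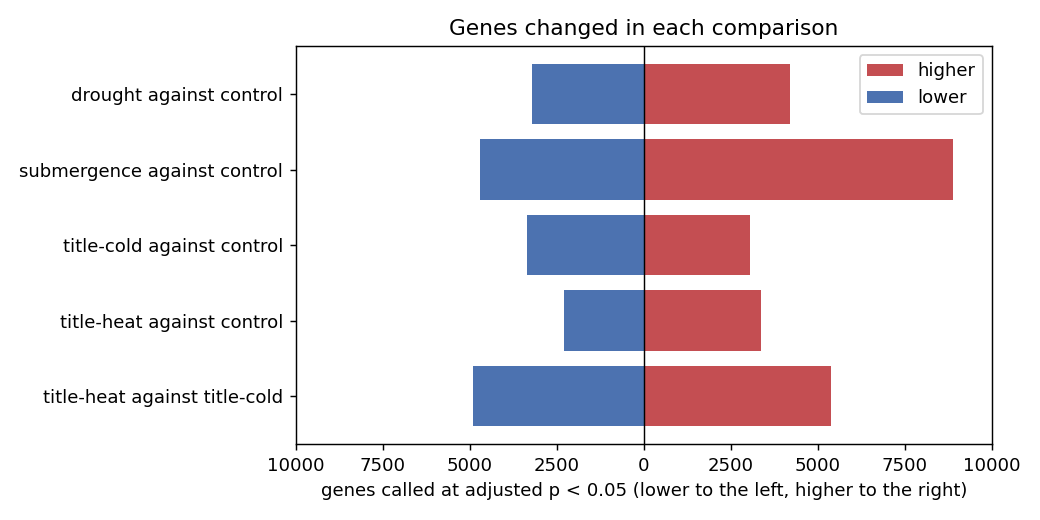
Number of genes called higher and lower in each of the 5 comparisons at an adjusted p below 0.05, edgeR. Submergence has the most calls against control, 8885 higher and 4716 lower.

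The genes most abundant over all libraries behaved differently between treatments. Of the 100 most abundant genes, 87 fell and 9 rose under submergence, and 70 fell and 8 rose in title-cold. The genes were ranked by level over these same 10 libraries, so the choice itself can favour a fall in a group unlike the rest. Under drought 18 fell and 12 rose, with 10 and 7 without control replicate 1 6 rising without control replicate 2 or drought replicate 2, and 28 falling and 7 rising with upper-quartile factors. In title-heat 6 fell and 14 rose, a direction that turned to 15 and 13 with upper-quartile factors and to 22 and 13 with total counts, while 1 fell without control replicate 1 or title-heat replicate 1 and 2 without title-heat replicate 2. With a library of the comparison left out in turn, 82 to 86 of these genes fell under submergence and 60 to 70 in title-cold, and total counts gave 80 and 52. The rising genes in title-cold numbered 17 with total counts in place of 8. In the direct comparison 76 were higher in title-heat than in title-cold and 6 lower, and total counts gave 52 and 16. Together these genes held 48.5 ± 2.3% of the counts in control, 42.5 ± 0.62% under drought, 23.5 ± 1.7% under submergence, 39.2 ± 0.32% in title-cold and 42.3 ± 1.2% in title-heat (SD, n = 2). Between TMM and total counts, the log2 fold change of a gene moved by a median over genes of 0.63 for submergence, 0.55 for title-cold, −0.16 for title-heat and −0.71 for the direct comparison. Between TMM and upper-quartile factors this median move was −0.2 for drought and submergence and −0.15 for title-heat.

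Treatments shared many called genes, and drought and title-heat shared theirs most often in one direction. Both raised 1956 genes, where independent lists would share 514.6, and both lowered 968, against 268.6, while 261 genes went in opposite directions, against 745. Submergence and title-cold shared 1523 higher genes (981.9 for independent lists) and 2096 lower genes (575.8), with 576 opposite (1606). Drought and submergence shared 1759 higher (1352) and 1494 lower genes (551.3), with 883 opposite (1756). Submergence and title-heat shared 1437 (1090) and 993 (393.1), with 815 opposite (1319). The 3650 tested submergence-only genes enter these expected numbers, although 0 counts elsewhere keep them from being called in other treatments. Expected numbers of shared higher genes are thus too high for pairs with submergence, and the other one-direction expected numbers too low. Drought and title-cold shared 822 higher (463.5) and 927 lower genes (393.5), with 972 opposite (868.2). Title-cold and title-heat shared 774 (373.9) and 632 (280.6), with 908 opposite (667). In both of these pairs opposite calls also exceeded the number printed for independent lists. That number is too low here as well, because the submergence-only genes enter it. For drought and title-cold, 972 against 868.2 is therefore not taken as an excess. Simulated unchanged groups with shared simulated controls gave at most 0.05 shared calls per data set. With no gene changed there are few calls to share, so this cannot show how much overlap the shared controls add. Part of the excess may come from the shared controls, which could not be split into parts of 2 libraries. Without control replicate 1 or 2 the genes shared in one direction became 1870 or 1970 for drought and submergence (3253 with all libraries), 890 or 967 for drought and title-cold (1749), 1282 or 1386 for submergence and title-heat (2430) and 633 or 748 for title-cold and title-heat (1406), and 2133 without control replicate 1 for submergence and title-cold (3619). Without title-heat replicate 1 or 2 they were 1289 or 1320 for submergence and title-heat and 719 or 699 for title-cold and title-heat. Opposite calls also fell without control replicate 1 or 2, to 119 or 107 for drought and title-heat, 422 or 408 for drought and title-cold, 262 or 260 for submergence and title-cold and 435 or 419 for title-cold and title-heat. Without title-heat replicate 1 or 2 they were 154 or 143 for drought and title-heat and 518 or 519 for title-cold and title-heat, and without title-cold replicate 2 they were 643 for drought and title-cold and 379 for submergence and title-cold. No filter gave 454 opposite calls for drought and title-heat, and limma-voom gave 4189 for submergence and title-cold, where 3672 of its title-cold calls had 0 counts in both title-cold and control and edgeR called 0 of these.

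Fold changes across genes were most alike between drought and title-heat. Their covariance was 0.942 and the simulated one 0.19, a difference of 0.751, with r = 0.53 against a simulated 0.5. For submergence and title-cold the difference was 0.512, for submergence and title-heat 0.401, and for drought and submergence 0.383. It was 0.0756 for title-cold and title-heat and 0.0511 for drought and title-cold. Observed r of these 5 pairs was 0.15 to 0.27 and simulated r 0.51 to 0.52. A simulated r near 0.5 follows from the shared controls when no gene changes, so observed r cannot be judged against it. Without genes read almost only under submergence, r was 0.31 in place of 0.2 for drought and submergence, 0.4 in place of 0.27 for submergence and title-cold and 0.31 in place of 0.21 for submergence and title-heat, and it was 0.53 for drought and title-heat. With a different single control library in each comparison, r for drought and title-heat was 0.412 and 0.388, and the other pairs gave 0.0156 to 0.195.

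A smaller group of genes changed in all 4 treatments. Of 19345 genes called in any comparison with control, 1040 were called in all 4, with 287 higher and 299 lower in every one, where independent lists would give 18.3 and 5.61. The 287 higher genes had a median of 6.82 CPM in control and rose by a median log2 change of 1.74 under drought, 1.8 under submergence, 1.35 in title-cold and 1.6 in title-heat. The 299 lower genes were more abundant in control, with a median of 79.5 CPM, and their median changes were −1.13, −2.09, −1.36 and −1.04. A gene near 0 counts in control can hardly be called lower, and 12 of the 287 higher genes had 0 counts there. The choice of genes itself thus favours this contrast in control level. These 4 comparisons share their control libraries, and part of the excess may come from them. The nearly even split depended on scaling, with 180 higher and 520 lower genes under upper-quartile factors and 478 higher and 217 lower under total counts. The 586 genes in all became 229 or 280 without control replicate 1 or 2 and 272 or 289 without title-heat replicate 1 or 2. The counts shared in one direction by drought and title-heat, 2924 in all, became 1651 or 1608 without control replicate 1 or 2 and 1671 or 1748 without title-heat replicate 1 or 2.

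**Figure D5:**
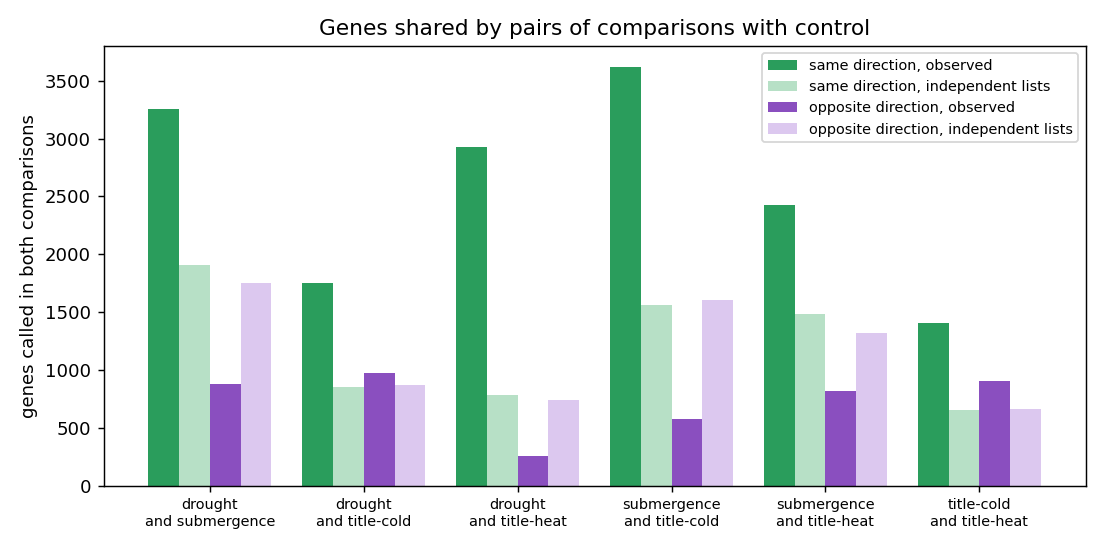
Genes called in both comparisons of each pair, in the same direction (green) and in opposite directions (purple), with pale bars for the number that independent lists of the same sizes would share. Drought and title-heat share 2924 genes in one direction and 261 in opposite directions, where independent lists give 745 opposite.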

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

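The temperature groups moved 908 genes to opposite sides of control, where independent lists would give 667. The latter number is too low, because submergence-only genes, which cannot be called in these groups, enter it. All 908 were also called in the direct comparison of the groups, which follows almost by construction from choosing genes called on opposite sides of the same control and so adds little evidence. Of them, 719 were higher in title-heat and lower in title-cold, and 189 were the reverse. Among the 719, drought raised 393 and lowered 70, and submergence raised 141 and lowered 331. Among the 189, drought raised 20 and lowered 63, and submergence raised 56 and lowered 42. The number of opposite genes became 435 or 419 without control replicate 1 or 2 and 518 or 519 without title-heat replicate 1 or 2. Since the labels of these groups contradict each other, which temperature each direction belongs to was not settled here.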

How the results depend on the processing

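Of 968 values under alternatives for 54 results, 746 stayed within 1.5 times their main value or on their side of the threshold, and 222 counts moved further. The genes lower and higher in all 4 enter this tally again as genes above and below each other group in control. Reversal was defined for the 4 named genes, of which 0 reversed, and not for counts, although scaling turned the balance of higher and lower in several of them. The 4 named genes stayed past the threshold with their direction under each alternative that tested them (highest adjusted p 4.23e-05 for c123165.graph_c0, 0.000108 for c141899.graph_c0, 0.000201 for c159807.graph_c0, 0.00889 for c82852.graph_c0), and c159807.graph_c0 was not tested under the stricter filter. A test against a fold of 1.5, stricter by construction, called 4410 genes for drought, 3693 for title-cold and 3399 for title-heat, 145 in one direction in all 4, and for the pairs 1573 (drought and submergence), 644 (drought and title-cold), 1508 (drought and title-heat), 2012 (submergence and title-cold), 1216 (submergence and title-heat) and 574 (title-cold and title-heat). limma-voom called 10184 for title-cold, 3672 of them with 0 counts in both groups and 6512 others. The stricter filter, with fewer genes tested, gave 8640 for submergence. No filter gave 2157 for title-cold and title-heat, and total counts gave 5523 for submergence and title-cold; the cause was not tested. Without genes read almost only under submergence, an alternative added after seeing the data, submergence gave 9045, and without the submergence-only genes 9231. Without the submergence libraries, also added, drought, title-cold, title-heat and the direct comparison gave 7377, 6315, 5653 and 9992. DESeq2 gave 6434, 9164, 5436, 5105 and 8543 for the 5 comparisons. Leaving out each library gave 4463 to 5895 for drought, 7934 to 9399 for submergence, 3727 to 4435 for title-cold, 3020 to 3361 for title-heat, 6525 to 7941 for the direct comparison and 229 to 547 for all 4. For the pairs, in the order above, it gave 1870 to 3132, 890 to 1584, 1608 to 2792, 2133 to 3582, 1282 to 2476 and 633 to 1430. A lone library was assumed to vary like the other groups; at least 51.6% of calls were kept, and at most 1 call turned its direction under any alternative. Replicate numbers did not pair the samples (10 correlations of deviations from −0.0164 to 0.0389, 8 above 0, so not every library correlated best with its own number). With the replicate block the counts were 6720, 10946, 5717, 5036 and 9322, and 512 in all 4. Among the other counts, the test against a fold of 1.5 lowered 26, no filter raised 8, and total counts raised 9 and lowered 5. The alternatives for the gene lists were not run because 0 members were matched. With 2 libraries per group, 2-fold changes are often missed. Leaving out a library lowers the power of each comparison it enters, so fewer calls then do not single out a library.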

Other observations

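Several genes stood at one end of all groups. Submergence had 5519 genes above each other group and 1701 below, drought 1153 and 665, title-cold 838 and 1079, title-heat 855 and 498, and control 299 and 287. Of the 5519, 1693 lay outside the genes read almost only under submergence, and a new fit without those genes gave 1552. The stricter filter gave 1381 and the replicate block 3594. The 5519 became 3590 or 3513 without control replicate 1 or 2, 2189 or 2277 without submergence replicate 1 or 2, and 3252 or 3303 without title-heat replicate 1 or 2, and the 1701 became 1114 without submergence replicate 1. For drought, the 1153 became 670 without drought replicate 2 and 666 or 548 without title-heat replicate 1 or 2, and the 665 became 398 without control replicate 2, 382 without drought replicate 2 and 378 or 349 without the title-heat ones. The 838 became 408 or 495 without control replicate 1 or 2, 501 or 496 without the submergence ones, 454 or 382 without the title-cold ones and 507 or 496 without the title-heat ones. For title-heat, the 855 became 510 or 490 without title-heat replicate 1 or 2. The 498 became 329 without control replicate 1 and 255 or 181 without title-heat replicate 1 or 2. For control, the 299 became 117 or 152 and the 287 became 112 or 128 without control replicate 1 or 2, and 119 or 134 and 153 or 155 without the title-heat ones, with 187 for the latter without title-cold replicate 2. The balance of genes above and below also moved with scaling. With total counts the balance turned in title-cold, to 1581 above and 593 below, in title-heat, to 603 and 829, and in control, to 217 and 478, and submergence had 985 below. With upper-quartile factors control had 520 above and 180 below. limma-voom, which called 3672 genes with 0 counts in both title-cold and control, gave 4580 below for title-cold, and DESeq2 gave 486 above for it and 2501 above for submergence.

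In 3 patterns technical explanations were tested against the treatments. The tests of sequencing depth and of identifier sharing under equal selection were chosen only after the result was seen.

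The first pattern is the set of 3895 genes read only in the submergence libraries. Sequencing depth is argued against, since 3695 such genes were left after both submergence libraries were thinned to the smallest total of the others. RNA of another organism stays open and has values in its favour. Of 1459 genes of the set that could be matched on level, 4.25% had a gene read in the other libraries under the same identifier number, 0.18 times the 23.6% of genes that rose under submergence from reads in control (interval 0.13 to 0.24). Because choosing genes at exactly 0 elsewhere can itself remove such sharing, genes with 0 counts in control were compared between stresses, and the share was 3.37% (2.83 to 3.98) under submergence, 10.3% (5.41 to 17.2) in title-cold, 17.4% in drought and 19.2% in title-heat, a ratio of at most 0.327. What identifier numbers mean is not stated in the sources used here and no sequences were used, so ryegrass genes switched on by submergence may also account for the set.

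The second pattern is the set of calls shared by drought and title-heat. Shared control libraries as the whole cause are argued against, since with a different control library in each comparison the fold changes still correlated across genes at r = 0.412 and 0.388. The other 5 pairs gave 0.0156 to 0.195. A response common to both treatments remains a hypothesis, because it was found and tested on the same libraries. Growth or harvest conditions common to both groups were not tested. The age of the control seedlings is not given, so an age difference from control common to both groups stays open.

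The third pattern is the fall of abundant genes under submergence and in title-cold. Scaling of the libraries as the whole cause is argued against, since with total counts alone 80 and 52 of the 100 genes were still called lower, and the smaller ratio to the TMM counts was 0.743. The size of the fall did depend on scaling, with a median log2 change over the 100 genes of −1.35 in place of −1.99 under submergence and −0.573 in place of −1.13 in title-cold, so scaling stays open as part of it. Ranking the 100 genes over these same libraries can also favour a fall in a group unlike the rest, which was not tested. Under submergence, RNA of another organism may take part of the counts, and its share is not known. Such a loss would lower ryegrass genes alike with total counts. There the median tested gene, with submergence-only genes included, was 0.92 higher on the log2 scale. The 100 genes also fell less there (−1.35) than with TMM factors (−1.99). These values argue against such a loss as the source of the larger fall with TMM, while a part of the fall with total counts stays open. The submergence-only genes held 2.2% of the counts. The 4375 genes with a fitted log2 rise of at least 5, which include 3650 of that set, held 12.3 ± 0.64% (SD, n = 2). Fitted rises of genes without reads in control depend on the prior count. With such genes set at their bound, 749 genes had a log2 rise of at least 5, and the share of counts they held is not given here.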
